A study of Mus musculus with 24 samples.

How the data were processed

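RNA of 24 sorted cell samples from mice on postnatal day 10 was made into libraries with the SMART-Seq v4 and Nextera XT kits, per the labels' protocols. These kits amplify cDNA without marking the strand, so reads of overlapping genes on opposite strands are not told apart. The submitters' processing notes name bcl2fastq 2.19, STAR 2.5.2 and Cufflinks 2.1.1 and the mouse build GRCm38. The values used here are FPKM as deposited by the authors in a single file of protein-coding genes, per the file headers, with a column for each library. FPKM divides by gene length and by the mapped fragments of the library, so a few abundant genes can shift all others, and the read depth behind a value is unknown. An exact 0 can be a failed estimate, so genes are called listed at 0.

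The file held 22053 gene entries. Those that repeated an identifier (46) or a symbol (56) were left out, as were 3 genes with a failed estimate in some library, Apoe, Apbb2 and 9530068E07Rik, whose 16 failed values were all 0. This left 21948 genes, of which 21739 matched the reference annotation by identifier. Values marked as low data (960 values in 40 genes) were kept. Start positions in the file were taken to count from 0, and 1 was added to them, since 17886 of the 21739 matched genes start 1 below the reference annotation, 180 start at its position and the rest at neither.

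Groups were taken from the titles, except for the 4 vertebral GFP- EMB+ libraries, whose titles disagree with their cell type labels and which were grouped by the latter. All titles of the long bone EMB+ libraries carry replicate number 1, so numbers only name these libraries. Within groups, no pair of libraries was a duplicate (smallest median difference 0.143 on the log2 scale). Pairs across groups were not compared.

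Genes with an FPKM of 1 or more in at least 4 of the 24 libraries were tested, 11768 in all, on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3. A single fit over the 6 groups, with 18 residual degrees of freedom, used empirical Bayes moderation with a trend and robust estimation (median prior degrees of freedom 6.66). Tests were two-sided with Benjamini-Hochberg adjustment at 0.05 within each of 9 comparisons and 2 differences of differences. Fold changes on this scale understate the change of low genes. Of 29 gene lists, 28 had at least 3 tested genes and were tested in each comparison with camera in limma, with a preset correlation between genes of 0.01 and, as an alternative, an estimated correlation, both with Benjamini-Hochberg adjustment over the lists. The groups, tests, gene lists and naming rule and the alternatives were chosen before the data were examined, except where a setting is said to be added later. Which lists are described, and which genes have their levels printed, was chosen after the results were seen.

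The genes named were fixed by rule: the genes of the sort markers; in each direction the 8 genes with the largest change past the threshold whose groups did not overlap and whose mean FPKM was 5 or more in the higher group, leaving out predicted genes; and up to 4 members of each described list with the smallest adjusted p. For the differences, 5 per direction were named without the condition on overlap. Groups of 4 and 4 fail to overlap by chance in 2.86% of unchanged genes. Mki67 and Mfge8 were chosen after their values were seen. Not every gene that the rule names is reported here.

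Alternatives were pseudocounts of 0.1 and 5, no filter (17617 genes), a stricter filter of FPKM 5 or more in at least 4 libraries (8057 genes), quantile normalization, median-ratio scaling over 4842 genes with an FPKM above 5 in every library, a fit of only the compared groups, library weights, the replicate number as a block (in long bone, added later, neighbouring codes of the titles), a fit without the libraries with conflicting labels, and each library left out in turn. Replicate numbers were taken to pair libraries where every same-numbered pair of 2 groups had deviations from the group means correlated above 0.1. This held for GFP+ and GFP- EMB+ cells (0.169 to 0.337), GFP+ and GFP- EMB- cells (0.130 to 0.292), EMB+ and EMB- vertebral GFP- cells (0.135 to 0.236), GFP+ EMB+ and GFP- EMB- cells (0.200 to 0.248) and GFP+ EMB- and GFP- EMB+ cells (0.104 to 0.185). The pairing comes from the numbers in the titles, and nothing says what they share. Running codes in the vertebral titles also place the libraries of each number side by side. The main fit holds no block, so it leaves this pairing out.

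The test was checked on simulated data for EMB+ against EMB- in vertebral GFP+ cells, with 200 of 11768 genes changed. It recovered 83 of 100 genes changed 2-fold and 98 of 100 changed 4-fold, and 10 of the genes called (5.24%) were unchanged. The shifted tendon and ligament list was recovered (adjusted p = 1.3e-14) and 0 of 27 other lists were called. Genes were drawn independently, with the same spread in every group and far fewer changes than in the data. The check therefore does not show how often lists of correlated genes are called falsely. Other tools were the R package data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Raw reads and non-coding genes were not analysed here.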

Results

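RNA was sequenced from skeletal stem and progenitor cells sorted from male mice on postnatal day 10. The cells came from vertebrae or from long bones and carried none of CD45, Ter119 (both blood cell markers), CD31 (endothelium), Thy1, 6C3 (the product of Enpep) or CD105 (the product of Eng), and they carried CD200. Each sample was further sorted on embigin (EMB), a surface protein encoded by Emb. Vertebral cells were also sorted on GFP driven by a Zic1-linked Cre, so that GFP+ cells belong to a lineage in which Zic1, a transcription factor of the dorsal body axis, has been active. The titles give all long bone cells as GFP-. Vertebral GFP+ against long bone cells thus differ in GFP state as well as in site. The 24 libraries fell into 6 groups of 4: vertebral GFP+ EMB+, vertebral GFP+ EMB-, vertebral GFP- EMB+, vertebral GFP- EMB-, long bone EMB+ and long bone EMB-. From what is known of the study, the question was how vertebral stem cells differ from those of long bones and what embigin separates among them. The sample titles call the replicates biological, and nothing further says that they came from separate animals, so the p-values measure the spread between these libraries.

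The values were FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of each library), so the number of reads per library is unknown and no counting intervals are given. The FPKM of a library summed to between 382613 and 569545, and 10158 to 11207 genes had an FPKM of 1 or more. The 10 most abundant genes held 18.6% to 30.7% of the summed FPKM. Col2a1, the main collagen of cartilage, and Sparc, a matrix protein of bone, together held 20.6% ± 0.444 (SD, n = 4) in vertebral GFP+ EMB- cells and 20.8% ± 0.578 in vertebral GFP- EMB- cells, against 13.4% ± 0.235 and 12.6% ± 0.409 in the matching EMB+ groups. Hemoglobin genes held 6.88% ± 1.74 in long bone EMB- cells and 2.34% ± 0.485 in vertebral GFP- EMB- cells, and between 0.0837% and 0.171% on average in the other 4 groups. Long bone EMB- replicate 4 stood apart from the other 3 libraries of its group: its lowest correlation with them over genes was 0.925, while within the other groups no pair fell below 0.978.

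Emb and Zic1 RNA followed the sort. Emb (chromosome 13, 117220625 to 117274098, GRCm38) averaged 50.0 ± 4.41 FPKM (SD, n = 4) in vertebral GFP+ EMB+, 49.5 ± 4.70 in vertebral GFP- EMB+ and 34.7 ± 4.58 in long bone EMB+ cells, and 0.398 ± 0.126, 1.03 ± 0.206 and 0.930 ± 0.173 in the respective EMB- groups. The titles and the cell type labels of the 4 vertebral GFP- EMB+ libraries disagree, and they were grouped by the cell type label. These titles give the cells as Emb-. Emb levels of 44.4 to 55.3 FPKM in the 4 libraries argue against that, since no library of an EMB- group exceeded 1.32. Zic1 (chromosome 9, 91358058 to 91365810) was low: 1.87 ± 0.396 FPKM in vertebral GFP+ EMB+ and 0.827 ± 0.430 in vertebral GFP+ EMB- cells. It reached at most 0.108 FPKM in any vertebral GFP- library and was listed at 0 in all 8 long bone libraries. Thy1, Ptprc (CD45) and Pecam1 (CD31) fell below the expression filter, and Cd200 averaged between 97.8 ± 12.2 and 298.0 ± 178 FPKM across the groups. Eng averaged between 1.30 ± 0.516 and 1.87 ± 0.324 FPKM and passed the test in none of the 9 comparisons, though with quantile normalization it was higher in vertebral GFP+ than in long bone EMB- cells (adjusted p = 0.0093). Enpep averaged 0.956 ± 0.341 and 1.27 ± 0.423 FPKM in long bone EMB+ and EMB- cells and at most 0.385 ± 0.171 in the vertebral groups. It was lower in vertebral cells, by -0.71 (adjusted p = 0.00050) in GFP+ EMB+, -0.73 (0.00017) in GFP+ EMB-, -0.49 (0.016) in GFP- EMB+ and -0.71 (0.00026) in GFP- EMB- cells. The third of these calls was lost in the fit of only the compared groups (0.0505), without vertebral GFP- EMB+ replicate 4 (0.0644) and without long bone EMB+ replicate 3 (0.0547) or 4 (0.0677). All 4 Y-linked genes examined, Ddx3y, Eif2s3y, Kdm5d and Uty, were above 0 in all 24 libraries.

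**Figure D1:**
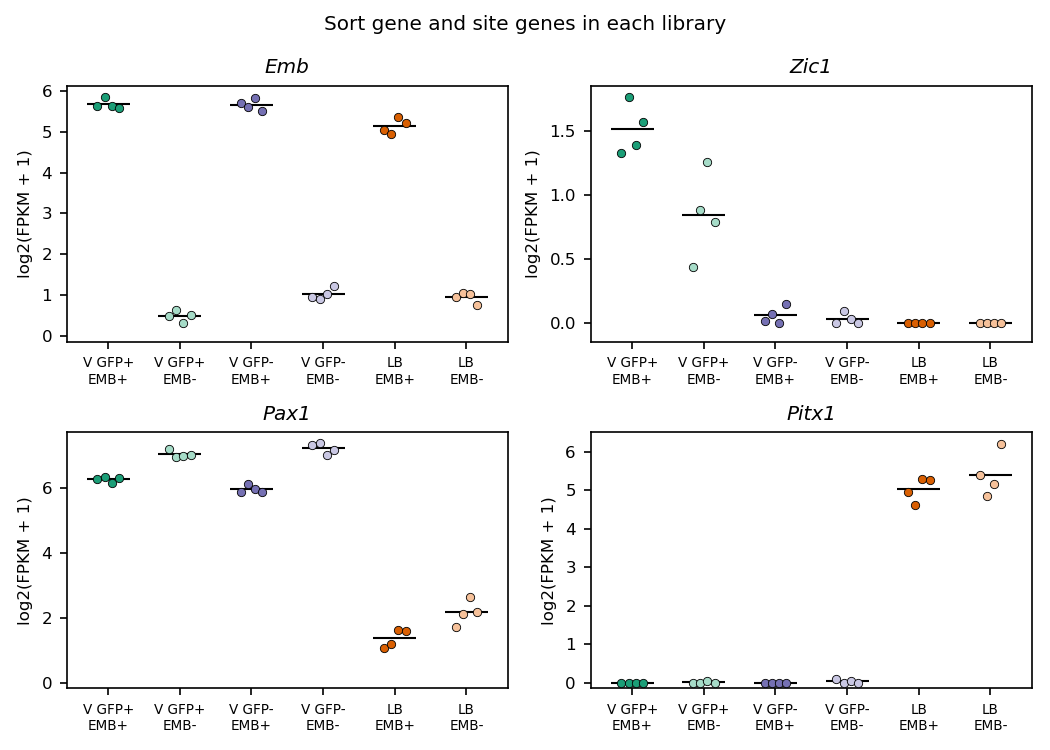
Level of Emb, Zic1, Pax1 and Pitx1 in each of the 24 libraries, as log2(FPKM + 1) on the vertical axis, by sorted group (V, vertebra; LB, long bone). Points are libraries and lines are group means. Emb separates EMB+ from EMB- groups, Zic1 is above 0 in every vertebral GFP+ library, Pax1 is highest in vertebral cells, and Pitx1 averages 32.2 and 43.7 FPKM in the long bone groups and at most 0.0705 FPKM in any vertebral library.

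In the vertebral GFP+ lineage, EMB+ cells held more RNA of Col10a1, Ihh and Wnt11 than EMB- cells, and less RNA of tendon and ligament and of fibroblast and periosteum genes. Col10a1, the collagen of hypertrophic cartilage (chromosome 10, 34389981 to 34397085), averaged 122.1 ± 26.6 FPKM in EMB+ and 2.75 ± 1.10 in EMB- cells and rose by 5.06 on the log2(FPKM + 1) scale, which understates the change of low genes (SE 0.33, adjusted p = 1.5e-11). Ihh, the Hedgehog ligand of prehypertrophic chondrocytes, rose by 3.71 (SE 0.20, adjusted p = 2.7e-13), from 9.49 ± 2.86 to 132.5 ± 9.96 FPKM, and Wnt11, a Wnt ligand, by 3.68 (SE 0.24). Cilp, a cartilage intermediate layer protein, fell by 4.77 (SE 0.27, adjusted p = 5.4e-13), to 5.97 ± 0.815 FPKM. Tnmd, a marker of mature tendon and ligament cells, fell by 3.70 (SE 0.21, adjusted p = 5.2e-13), from 162.7 ± 27.4 to 11.6 ± 2.20 FPKM, and Eln, which encodes elastin, fell by 3.87 (SE 0.23).

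Over all genes, 5882 of 11768 changed in this comparison, 4958 higher and 924 lower in EMB+ cells, and 752 and 358 of them by 2-fold or more. The median gene shifted by 0.32 on the log2 scale. After median-ratio scaling, which removes that shift, 3246 genes changed, 1522 higher and 1724 lower, so the larger side flipped with the scaling. The 16 genes with the largest changes kept their direction and their call under both scalings tried, and median-ratio scaling lowered their log2 changes by 0.21 to 0.39.

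By gene list, 19 of 22 chondrocyte genes rose and 1 fell (the same adjusted over the list alone). Their median change was 1.20 and the list's adjusted p 2.4e-06, but adjusted p = 0.392 with an estimated correlation. After median-ratio scaling 13 rose and 1 fell, with a median of 0.81. Matn3, which encodes matrilin 3, rose by 2.59. All 10 tendon and ligament genes fell, with a median of -1.86 (adjusted p = 4.6e-17 and adjusted p = 0.00022 with an estimated correlation), among them Scx, the tendon transcription factor scleraxis, with -2.03 and Thbs4, a tendon matrix thrombospondin, with -3.69. Of 13 fibroblast and periosteum genes 12 fell, all 12 adjusted over the list alone, with a median of -2.05 (adjusted p = 1.7e-20 and adjusted p = 0.0017 with an estimated correlation), including Postn (periostin) with -2.77 and Col3a1 with -2.21. Of 30 cell cycle genes 29 rose, also adjusted over the list alone, with a median of 1.64 (adjusted p = 6.6e-10 and adjusted p = 0.561 with an estimated correlation). After median-ratio scaling 28 rose and 1 fell. Top2a, the topoisomerase of dividing cells, rose by 2.46. The 19 osteoblast genes went both ways, 10 higher and 4 lower, and as a list did not differ from other genes (adjusted p = 0.568). Runx2, the osteoblast transcription factor, rose by 1.99 and Dlx5 by 2.57. None of the 11 erythroid genes passed the test, but 5 were lower without vertebral GFP+ EMB- replicate 1 and 6 with the replicate number as a block. Their median was -0.53 and the list's adjusted p 0.0075, lost with an estimated correlation (adjusted p = 0.741), under both scalings (0.153 and 0.166) and without vertebral GFP+ EMB+ replicate 1 (0.0534). Of 17 leukocyte genes 3 rose, 2 over the list alone, Cd74 by 1.87 and Cd79a by 0.84, and the list did not pass (adjusted p = 0.783). The third, Mpo (adjusted p = 0.042), averaged 3.29 ± 2.31 FPKM in EMB+ cells and was listed at 0 in all 4 EMB- libraries. Its call was lost under both scalings (0.080 and 0.082), with a pseudocount of 5 (0.277), with no filter (0.0504), and without vertebral GFP+ EMB+ replicate 1, 2 or 3 or any EMB- replicate (0.0554 to 0.119). S100a8 averaged 49.8 ± 40.1 FPKM in EMB+ and 29.1 ± 9.72 in EMB- cells.

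In the vertebral GFP- cells, EMB+ libraries held more RNA of Arsi, Col10a1, Ihh and Panx3, while EMB- libraries held more RNA of tendon and ligament, fibroblast and periosteum, and erythroid genes. Col10a1 rose by 5.41 (SE 0.33, adjusted p = 2.8e-12), Ihh by 4.83 (SE 0.20, adjusted p = 1.3e-15) and Panx3, a channel protein of osteoblasts and hypertrophic chondrocytes, by 4.29 (SE 0.16, adjusted p = 2.3e-16). Ihh averaged 159.1 ± 9.21 FPKM in EMB+ and 4.80 ± 1.66 in EMB- cells. Arsi, an arylsulfatase, rose the most, by 5.55 (SE 0.13), from 1.65 ± 0.274 to 123.9 ± 23.3 FPKM. Among the 8 genes that fell the most, Slc4a1, the anion exchanger of red cells, fell by 5.21 (SE 0.47, adjusted p = 7.8e-09), Hba-a1, an alpha globin, fell by 4.89 (SE 0.40, adjusted p = 4.8e-10), from 3284 ± 635 to 121.5 ± 55.0 FPKM. Car2, carbonic anhydrase 2, fell by 4.73 (SE 0.28). Hba-a1 and Hba-a2, as well as Hbb-bs and Hbb-bt, are near-identical copies, and their separate values are uncertain.

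In total 6152 genes changed, 4901 higher and 1251 lower in EMB+ cells, 893 and 543 by 2-fold or more. The median gene shifted by 0.30, and after median-ratio scaling 4125 changed, 1804 higher and 2321 lower. The 16 genes with the largest changes kept their direction and call under both scalings. The correlation across genes of the EMB log2 changes in GFP+ and GFP- vertebral cells, which share no libraries, was 0.736 (Spearman 0.665; genes are not independent replicates). In both comparisons 3539 genes rose, against 2064.9 for independent lists, 697 fell, against 98.2, and 72 went opposite ways. After median-ratio scaling 984 rose, against 233.3, and 1275 fell, against 340.0, and with quantile normalization 1178 and 1143, so the larger side depends on the scaling.

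Of the chondrocyte genes 17 of 22 rose and 1 fell, also adjusted over the list alone (median 1.00 and adjusted p = 1.7e-05 and adjusted p = 0.343 with an estimated correlation), and 13 rose and 2 fell after median-ratio scaling. Of 19 osteoblast genes 15 rose, also adjusted over the list alone, with a median of 2.09 (adjusted p = 9.5e-06 and adjusted p = 0.343 with an estimated correlation). With median-ratio scaling 14 rose and 2 fell. Mmp13, a collagenase of hypertrophic cartilage and bone, rose by 3.95, Dlx5 by 3.51 and Runx2 by 3.17. All 10 tendon and ligament genes fell, but 6 without vertebral GFP- EMB- replicate 2 (median -1.19 and adjusted p = 1.3e-09 and adjusted p = 0.0070 with an estimated correlation), Cilp with -4.36 and Tnmd with -1.82. So did 12 of 13 fibroblast and periosteum genes (median -1.33 and adjusted p = 4.7e-12 and adjusted p = 0.018 with an estimated correlation), Aspn (asporin) and Ogn (osteoglycin) each with -2.21. Beside these losses in EMB+ cells, all 11 erythroid genes fell with a median of -4.66 (adjusted p = 1.6e-19 and adjusted p = 0.018 with an estimated correlation). Of 30 cell cycle genes 10 fell and 1 rose, 9 and 1 adjusted over the list alone (median -0.25 and adjusted p = 1.9e-05 and adjusted p = 0.570 with an estimated correlation). After median-ratio scaling 16 fell and none rose, and with the replicate number as a block 14 fell and 3 rose. Without vertebral GFP- EMB- replicate 2 or 3, 6 and 5 fell. Rrm2, a ribonucleotide reductase subunit, fell by 1.58. Beside the gains, 13 of 17 leukocyte genes rose, 14 adjusted over the list alone. After median-ratio scaling 7 rose, 11 over the list alone, and with quantile normalization 8 and 12. Mpo, the myeloperoxidase of neutrophil precursors, rose by 3.90. As a list they did not pass (adjusted p = 0.163), but they did after median-ratio scaling (0.0036) and quantile normalization (0.010) and without vertebral GFP- EMB+ replicate 2 (0.024). Of 6 notochord genes 5 rose, also over the list alone (median 1.28 and adjusted p = 0.034 and adjusted p = 0.343 with an estimated correlation), Foxa2 by 2.14 and Krt8, a keratin, by 1.71. That call was lost with the replicate number as a block (0.218), with the stricter filter (0.114), with a pseudocount of 0.1 (0.350), with only the compared groups in the fit (0.138) and without long bone EMB- replicate 4 (0.0918).

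In long bone, EMB+ cells were marked by Msmp, which encodes a small secreted protein, and EMB- cells by erythroid genes. Msmp (chromosome 4, 43583216 to 43584494) averaged 931.8 ± 337 FPKM in EMB+ and 2.38 ± 1.45 in EMB- cells and rose by 8.10 (SE 0.33, adjusted p = 4.0e-15). In vertebral GFP+ cells Msmp went the other way, with 35.0 ± 14.6 FPKM in EMB- cells and a change of -1.41 (SE 0.33, adjusted p = 0.0014). The EMB difference of Msmp in vertebral GFP+ cells minus that in long bone was -9.51 (SE 0.47, adjusted p = 6.1e-13). Il17b, a cytokine, rose by 3.80 (SE 0.22), Col10a1 by 3.64 (SE 0.33, adjusted p = 4.5e-09) and Car12, a carbonic anhydrase, by 3.10 (SE 0.22). Hba-a1 fell by 6.49 (SE 0.40, adjusted p = 4.4e-12).

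Here 3941 genes changed, 2062 higher and 1879 lower, 269 and 834 by 2-fold or more. With median-ratio scaling 1433 were higher and 2158 lower, and with quantile normalization 2680 and 1812, so the larger side depends on the scaling. The fit on the 8 long bone libraries alone gave 2059 genes. The correlation across genes of the EMB changes with those in long bone was 0.256 (Spearman 0.288) for vertebral GFP+ and 0.598 (Spearman 0.496) for vertebral GFP- cells.

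Of the chondrocyte genes 13 of 22 rose and 2 fell, also over the list alone (median 0.49 and adjusted p = 0.00034 and adjusted p = 0.472 with an estimated correlation). In that fit of the 8 long bone libraries 4 rose and 1 fell, 6 and 1 over the list alone. Ihh rose by 2.56 and Epyc (epiphycan) by 2.49. Of 19 osteoblast genes 11 rose and 2 fell, also over the list alone (adjusted p = 0.00080 and adjusted p = 0.472 with an estimated correlation). Sp7, the osteoblast factor osterix, rose by 1.63 and Mepe, a protein of osteocytes, fell by 3.35. Of 10 tendon and ligament genes 7 fell, also over the list alone (median -1.04 and adjusted p = 0.00016 and adjusted p = 0.075 with an estimated correlation), among them Kera (keratocan) with -2.25. Of 13 fibroblast and periosteum genes 10 fell, also over the list alone (median -1.13 and adjusted p = 1.2e-07 and adjusted p = 0.075 with an estimated correlation), with Ly6a (Sca-1) at -3.13. All 30 cell cycle genes fell in EMB+ cells, with a median of -1.98 (adjusted p = 6.5e-27 and adjusted p = 0.075 with an estimated correlation). All 11 erythroid genes fell, with a median of -6.09 (adjusted p = 3.4e-20 and adjusted p = 0.0497 with an estimated correlation). Of 5 skeletal muscle genes 4 fell, also over the list alone where 1 rose (adjusted p = 0.00080 and adjusted p = 0.075 with an estimated correlation), among them Tnni2, a fast muscle troponin, with -3.14. Cd200, a gene of the sort, fell by 0.64 (adjusted p = 0.022), a call that was lost without long bone EMB- replicate 4 (adjusted p = 0.062), without long bone EMB+ replicate 4 (0.080) and in the fit on the 8 libraries alone (0.202).

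The cell cycle genes went opposite ways with EMB in the vertebral GFP+ lineage and in long bone, and the difference was tested directly. All 30 differed, with a median of 3.67 on the log2 scale (adjusted p = 2.6e-31 and adjusted p = 0.076 with an estimated correlation). All 11 erythroid genes differed as well, with a median of 5.65 (adjusted p = 2.0e-13 and adjusted p = 0.076 with an estimated correlation). Mki67, a proliferation gene chosen after its values were seen, averaged 2.22 ± 0.413 FPKM in EMB+ and 0.417 ± 0.0834 in EMB- vertebral GFP+ cells, 1.90 ± 0.354 and 3.95 ± 1.05 in vertebral GFP- cells, and 1.64 ± 0.340 and 14.2 ± 7.07 in long bone. Over all genes, the EMB difference differed between vertebral GFP+ cells and long bone for 3594 genes, 2938 higher and 656 lower. The median gene shifted by 0.23, and after median-ratio scaling 1647 were higher and 1213 lower, or 1496 and 1694 with quantile normalization. Between GFP+ and GFP- vertebral cells it differed for 573 genes, 377 higher and 196 lower, or 1850 with the replicate number as a block. There 27 of 30 cell cycle genes were higher, 29 over the list alone (median 1.91 and adjusted p = 6.9e-46 and adjusted p = 0.020 with an estimated correlation). All 11 erythroid genes were higher (adjusted p = 4.6e-30 and adjusted p = 0.0079 with an estimated correlation). Of 19 osteoblast genes 11 were lower, 14 over the list alone (median -1.07 and adjusted p = 1.6e-13 and adjusted p = 0.0435 with an estimated correlation).

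**Figure D2:**
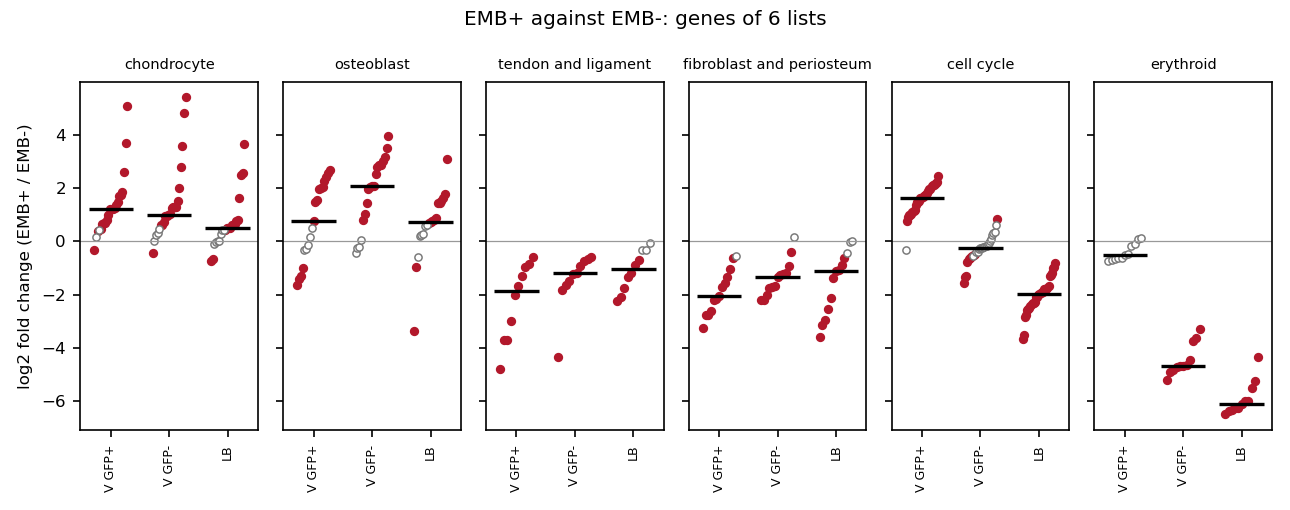
Log2 fold change of EMB+ against EMB- cells (vertical axis) for each gene of 6 lists, in vertebral GFP+ (V GFP+), vertebral GFP- (V GFP-) and long bone (LB) cells, 4 libraries per group. Red points passed an adjusted p of 0.05, white points did not, and lines are list medians. The cell cycle medians are 1.64, -0.25 and -1.98, and 1.42, -0.62 and -2.04 after median-ratio scaling, and the erythroid medians are -0.53, -4.66 and -6.09.

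**Figure D3:**
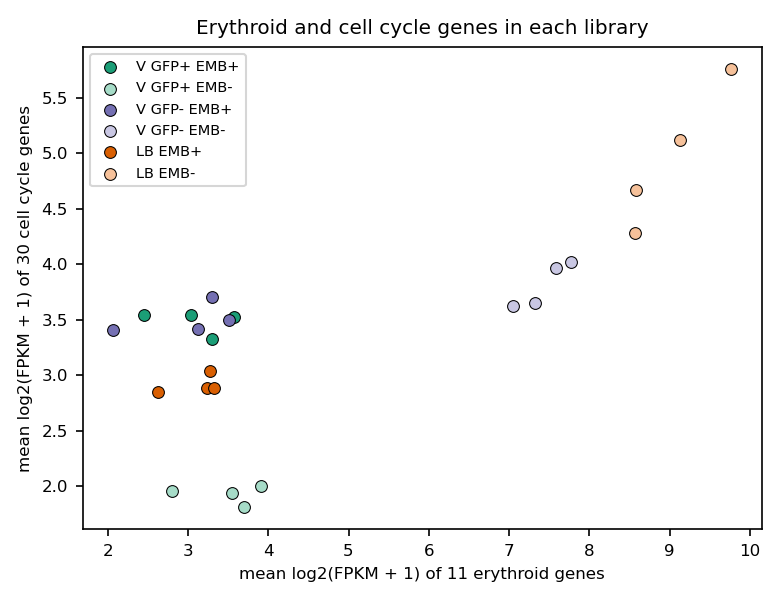
Mean log2(FPKM + 1) of 30 cell cycle genes (vertical axis) against that of 11 erythroid genes (horizontal axis), one point per library, coloured by group (V, vertebra; LB, long bone). The long bone EMB- libraries lie highest on both axes, with group means of 4.96 and 9.01, and the vertebral GFP+ EMB- libraries lie lowest for the cell cycle genes, with a mean of 1.93.

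GFP+ and GFP- cells of the vertebra were next compared within each EMB state. Among EMB+ cells the GFP+ lineage had more Zic1 and Zic4, and the GFP- cells had more RNA of notochord and leukocyte genes. Zic1 rose by 1.46 (SE 0.14, adjusted p = 4.9e-08), and Zic4 (chromosome 9, 91362413 to 91389348), its neighbour, averaged 5.58 ± 0.998 FPKM in GFP+ EMB+ libraries and was listed at 0 in 3 of the 4 GFP- EMB+ libraries. Nkx6-1, a homeobox factor, rose by 1.89 (SE 0.15, adjusted p = 1.1e-09). Krt8 (chromosome 15, 101996711 to 102004342), a keratin of notochord and other epithelial cells, fell by 4.98 (SE 0.23, adjusted p = 3.1e-14), from 44.8 ± 11.5 FPKM in GFP- to 0.436 ± 0.236 in GFP+ cells, and Krt19 fell by 4.56 (SE 0.19). Serpina1e, a protease inhibitor whose copies are so alike that its values are uncertain, fell by 5.30 (SE 0.16), while its relative Serpina1d rose by 1.58 (SE 0.20).

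Of 6 notochord genes 4 fell, also over the list alone, with a median of -3.17 (adjusted p = 3.7e-28 and adjusted p = 1.9e-06 with an estimated correlation), including T, the notochord transcription factor brachyury, with -3.65. T averaged 12.1 ± 1.76 FPKM in GFP- EMB+ cells and was listed at 0 in 3 of the 4 GFP+ EMB+ libraries. Beside them 13 of 17 leukocyte genes fell, 14 over the list alone (median -2.61 and adjusted p = 1.8e-24 and adjusted p = 0.0094 with an estimated correlation). With just the 8 compared libraries in the fit 3 fell, but still 14 over the list alone. Mpo fell by 4.77 (SE 0.76, adjusted p = 0.00072), from 130.6 ± 113 to 3.29 ± 2.31 FPKM, and S100a8, a calgranulin of neutrophils, fell by 4.21 (SE 0.81, adjusted p = 0.0046, but 0.152 in that fit). Among 9 sclerotome and axial factors the 2 that rose were Zic1 and Zic4, with 1 more falling over the list alone (adjusted p = 0.00029 and adjusted p = 0.037 with an estimated correlation, but 0.878 with the stricter filter, which removes Zic1 and Zic4). Of 20 immediate early genes 3 rose, 4 over the list alone, with a median of 0.27 (adjusted p = 1.9e-10 and adjusted p = 0.160 with an estimated correlation), among them Socs3 by 0.52. Only 1 rose without vertebral GFP+ EMB+ replicate 2 or without GFP- EMB+ replicate 1. With the replicate number as a block 14 of them rose, and the Hedgehog pathway list, not called otherwise (adjusted p = 0.052), passed (0.0071). In total 247 of 11768 genes changed, 46 higher and 201 lower, 12 and 120 by 2-fold or more. With the replicate number as a block 808 changed, 271 higher and 537 lower, with the stricter filter 136 and with library weights 451.

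Among EMB- cells the GFP+ lineage had more RNA of osteoblast genes and the GFP- cells more erythroid, cell cycle and notochord RNA. Bglap, the bone matrix protein osteocalcin (chromosome 3, 88383501 to 88384464), averaged 485.6 ± 112 FPKM in GFP+ and 142.4 ± 46.7 in GFP- cells and rose by 1.79 (SE 0.33, adjusted p = 0.00048). Bglap2, a near copy whose values are as uncertain as those of Bglap, rose by 1.80 (SE 0.30). Ifitm5, an osteoblast membrane protein, rose by 1.90 (SE 0.28, adjusted p = 1.6e-05) and Mmp13 by 1.66 (SE 0.26). Zic1 rose by 0.81 (SE 0.14, adjusted p = 0.00013), and Emb, already low in both groups, fell by 0.54 (SE 0.12, adjusted p = 0.0030), which was lost with a pseudocount of 5 (0.375). Car2 fell by 4.77 (SE 0.28, adjusted p = 1.1e-11) and Klf1, an erythroid transcription factor, fell by 4.17 (SE 0.24).

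Of 19 osteoblast genes 13 rose, 15 over the list alone (median 0.81 and adjusted p = 1.2e-16 and adjusted p = 0.0155 with an estimated correlation), among them Dlx5 by 1.15 and Runx2 by 1.10. All 11 erythroid genes fell (median -3.97 and adjusted p = 7.4e-31 and adjusted p = 0.0034 with an estimated correlation). All 30 cell cycle genes fell (median -1.88 and adjusted p = 1.5e-51 and adjusted p = 0.011 with an estimated correlation), such as Birc5, a chromosomal passenger protein, with -2.81. Of the notochord genes 5 of 6 fell, also over the list alone (median -1.76 and adjusted p = 2.8e-12 and adjusted p = 0.00071 with an estimated correlation), T with -1.96. Of 17 leukocyte genes 3 fell, 12 over the list alone, 6 with the replicate number as a block, 5 without vertebral GFP- EMB- replicate 1 and 1 without replicate 3 (adjusted p = 2.7e-06 and adjusted p = 0.142 with an estimated correlation). There were 7 with a pseudocount of 0.1, with library weights or with only the compared groups in the fit, 12, 12 and 14 over the list alone, and 1 with a pseudocount of 5, also over the list alone. Of 18 genes of secreted niche and tumour-recruiting factors 7 rose, 9 over the list alone where 1 fell (adjusted p = 3.9e-07 and adjusted p = 0.0155 with an estimated correlation), including Bmp4 by 1.38 (4 rose without vertebral GFP+ EMB- replicate 3) and Cxcl12, the chemokine that holds blood stem cells in the marrow, by 1.37. Of 18 skeletal stem cell markers 5 rose, also over the list alone (adjusted p = 0.00073 and adjusted p = 0.0155 with an estimated correlation), Pdgfra by 0.97 and Prrx1 by 0.73, and 3 rose without vertebral GFP+ EMB- replicate 1, 2 or 3 or GFP- EMB- replicate 3. Of 9 sclerotome and axial factors 3 rose, 4 over the list alone (adjusted p = 0.00056 and adjusted p = 0.025 with an estimated correlation, but 0.650 with the stricter filter, which leaves none that rose), Zic4 by 1.04. With the block, immediate early genes (adjusted p = 0.044) and limb factors (0.045) also passed as lists, against 0.102 and 0.054 without it. In total 997 genes changed, 265 higher and 732 lower, 61 and 392 by 2-fold or more. With quantile normalization 483 were higher and 683 lower. Library weights gave 1672 genes, and 2175 changed with the replicate number as a block, 792 higher and 1383 lower. Called in both GFP comparisons were 10 genes that rose, against 1 for independent lists, 49 that fell, against 12.5, and 10 that went opposite ways. After median-ratio scaling these were 17, against 1.6, 51, against 10.8, and 10.

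Vertebral and long bone cells differed in the genes that give position along the body. The titles of the sites carry separate runs of codes, so site cannot be told apart from how the libraries were prepared. Only the vertebral GFP- cells match the long bone cells in GFP state. In EMB+ cells, Pax1, a factor of the sclerotome from which vertebrae form (chromosome 2, 147361925 to 147393295), averaged 76.4 ± 4.27 FPKM in vertebral GFP+, 61.9 ± 5.32 in vertebral GFP- and 1.64 ± 0.495 in long bone cells, and was higher by 4.89 (SE 0.15, adjusted p = 3.7e-18) and 4.59 (SE 0.15, adjusted p = 1.2e-17). Hoxb7 was higher by 4.20 (SE 0.15) and 4.02 (SE 0.15). Shox2, a factor of the proximal limb (chromosome 3, 66971727 to 66981771), averaged 45.4 ± 2.91 FPKM in long bone and was lower in vertebral cells, by -5.41 (SE 0.15, adjusted p = 4.7e-19) in GFP+ and -5.11 (SE 0.15, adjusted p = 9.4e-19) in GFP- cells. Pitx1, the hindlimb factor (chromosome 13, 55825051 to 55836192), averaged 32.2 ± 6.77 FPKM in long bone EMB+ cells and was listed at 0 in all 8 vertebral EMB+ libraries. Tbx1, a T-box factor, averaged 29.7 ± 0.754 FPKM in vertebral GFP- and 0.0417 ± 0.0833 in long bone EMB+ cells, and T was higher there by 3.67 (SE 0.14).

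In EMB+ cells 15 of 16 Hox genes of groups 1 to 8 were higher in vertebral GFP+ than in long bone cells, also over the list alone (median 1.27 and adjusted p = 1.1e-19 and adjusted p = 0.0015 with an estimated correlation), and 15 of 16 in vertebral GFP- cells (median 1.11 and adjusted p = 4.1e-18 and adjusted p = 0.0012 with an estimated correlation). Of 9 Hox genes of groups 9 to 13, 5 were lower and 1 higher in GFP+ cells, 6 and 1 over the list alone (adjusted p = 0.029 and adjusted p = 0.381 with an estimated correlation). That call was lost without vertebral GFP+ EMB+ replicate 1 (0.078), with no filter (0.207) and with only the compared groups in the fit (0.058). In GFP- cells 5 were lower and 2 higher, 6 and 2 over the list alone (adjusted p = 0.0045 and adjusted p = 0.234 with an estimated correlation, and 0.401 with no filter). Hoxa11, a gene of the middle limb segment, was lower by -2.24 and -1.94. Of 14 limb factors 10 were lower and 2 higher in GFP+ cells, also over the list alone (adjusted p = 4.8e-08 and adjusted p = 0.0033 with an estimated correlation), and 11 and 2 in GFP- cells (adjusted p = 3.6e-08 and adjusted p = 0.0030 with an estimated correlation). Tbx4, a hindlimb factor, was lower by -2.96 and -2.94, while En1 was higher in GFP+ cells by 1.64. Of 9 sclerotome and axial factors 6 were higher and 1 lower in GFP+ cells (adjusted p = 1.8e-08 and adjusted p = 0.0020 with an estimated correlation), and 4 and 1 in GFP- cells (adjusted p = 0.00014 and adjusted p = 0.020 with an estimated correlation), both also over the list alone. This list holds Zic1, on whose lineage the GFP+ cells were sorted, and its neighbour Zic4, both listed at 0 in all long bone libraries. Its result in GFP+ cells is therefore in part set by the sort.

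Skeletal genes also differed by site in EMB+ cells. Matn1, matrilin 1 of cartilage, averaged 541.2 ± 99.8 FPKM in long bone and was lower in vertebral GFP+ cells, by -4.65 (SE 0.19, adjusted p = 1.5e-15), and in GFP- cells, by -3.71 (SE 0.19). Ihh was higher by 2.24 and 2.51 and Chad (chondroadherin) by 2.46 and 2.27. Of 22 chondrocyte genes 16 were higher and 2 lower in GFP+ cells, 20 and 2 over the list alone (adjusted p = 3.6e-09 and adjusted p = 0.075 with an estimated correlation), and 18 and 2 in GFP- cells, 19 and 2 over the list alone (adjusted p = 2.5e-09 and adjusted p = 0.079 with an estimated correlation). Of 19 osteoblast genes 11 were lower and 4 higher in GFP+ cells, 12 and 4 over the list alone (adjusted p = 0.00079 and adjusted p = 0.314 with an estimated correlation), and 10 and 2 in GFP- cells, 11 and 4 over the list alone (adjusted p = 0.00051 and adjusted p = 0.265 with an estimated correlation), Col1a1, the main collagen of bone, by -2.37 and -2.03. In GFP+ cells 2 were higher without vertebral GFP+ EMB+ replicate 1 or 2 or long bone EMB+ replicate 3 or 4. Of 18 skeletal stem cell markers 9 were lower and 1 higher in GFP+ cells, also over the list alone (adjusted p = 0.00045 and adjusted p = 0.011 with an estimated correlation), and 10 were lower in GFP- cells, with 1 higher over the list alone (adjusted p = 7.8e-05 and adjusted p = 0.0057 with an estimated correlation), Cdh11, a cadherin of mesenchyme, by -1.80 and -1.62. Of 18 secreted niche and tumour-recruiting factors 11 were lower and 3 higher in GFP+ cells, 12 and 3 over the list alone (adjusted p = 0.00059 and adjusted p = 0.075 with an estimated correlation), and 11 and 2 in GFP- cells, also over the list alone (adjusted p = 2.7e-05 and adjusted p = 0.037 with an estimated correlation). Cxcl12 was lower by -1.96 and -1.66 and Bmp4 by -1.88 and -1.81, while Bmp2 was higher by 1.44 and 1.22. Mfge8, a secreted protein on that list because the study is known for it, was higher in vertebral cells in all 4 site comparisons, by 1.04, 1.03, 1.07 and 0.90 (adjusted p = 1.5e-05, 7.2e-06, 1.3e-05 and 4.9e-05 for GFP+ EMB+, GFP+ EMB-, GFP- EMB+ and GFP- EMB- cells). Mfge8 averaged 2659 ± 153 FPKM in vertebral GFP+ EMB+ and 1307 ± 254 in long bone EMB+ cells.

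Genes of signalling lists differed as well between the EMB+ cells of vertebra and long bone, where site cannot be told apart from preparation. Of 20 immediate early genes 15 were higher in vertebral GFP+ cells, 16 over the list alone (adjusted p = 1.7e-13 and adjusted p = 0.048 with an estimated correlation), and 13 in GFP- cells, 14 over the list alone (adjusted p = 3.5e-08 and adjusted p = 0.102 with an estimated correlation), with Dusp1, a phosphatase induced by stress, higher by 1.94 and 1.62. Of 8 Notch pathway genes 5 were lower in GFP+ cells (adjusted p = 0.00045 and adjusted p = 0.0073 with an estimated correlation) and 4 in GFP- cells (adjusted p = 0.00041 and adjusted p = 0.0068 with an estimated correlation), both also over the list alone, Hey1, a Notch target, by -1.24 and -1.11. In vertebral GFP- cells all 6 notochord genes were higher than in long bone, also over the list alone (median 3.01 and adjusted p = 3.5e-15 and adjusted p = 0.00016 with an estimated correlation), and 4 of 17 leukocyte genes were higher, also over the list alone (adjusted p = 9.0e-05 and adjusted p = 0.222 with an estimated correlation). The 4 became 9 without vertebral GFP- EMB+ replicate 2, 2 without its replicate 3 or long bone EMB+ replicate 3, and 1 without its replicate 1 or long bone EMB+ replicate 4. They became 8 with a pseudocount of 5, 2 with the stricter filter or only the compared groups in the fit, and 1 with a pseudocount of 0.1. Over the list alone these were 14, 11, 1 and 1. In GFP+ cells 7 leukocyte genes were lower and 2 higher, 9 and 2 over the list alone (adjusted p = 0.014 and adjusted p = 0.444 with an estimated correlation), a call lost without long bone EMB+ replicate 1 (0.0586) or 2 (0.0661). The 7 became 3 without vertebral GFP+ EMB+ replicate 2 or long bone EMB+ replicate 2, and 4 without long bone EMB+ replicate 1 or 3. Of 30 cell cycle genes 11 were higher in vertebral GFP+ than in long bone EMB+ cells, 20 over the list alone (median 0.57 and adjusted p = 2.1e-07 and adjusted p = 0.330 with an estimated correlation), and 10 in GFP- cells, 22 over the list alone (median 0.58 and adjusted p = 1.2e-07 and adjusted p = 0.281 with an estimated correlation), Top2a by 1.25 and 1.20. Without long bone EMB- replicate 4, which is in none of the compared groups but enters the shared estimate of the spread, 19 and 21 were higher. In GFP+ cells 6 were higher without vertebral GFP+ EMB+ replicate 2 or 3 or long bone EMB+ replicate 2, and 7 without vertebral GFP+ EMB+ replicate 1 or long bone EMB+ replicate 3. In GFP- cells 5 were higher without vertebral GFP- EMB+ replicate 3, and 6 without long bone EMB+ replicate 2 or 3. With only the compared groups in the fit 23 and 26 were higher, and with library weights 22 and 26. A pseudocount of 5 left 7 in GFP+ cells, 9 over the list alone. Changes in EMB+ cells numbered 2531 genes in GFP+ cells, 1017 higher and 1514 lower, or 1328 and 1301 with quantile normalization, and 2243 genes in GFP- cells, 998 higher and 1245 lower.

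**Figure D4:**
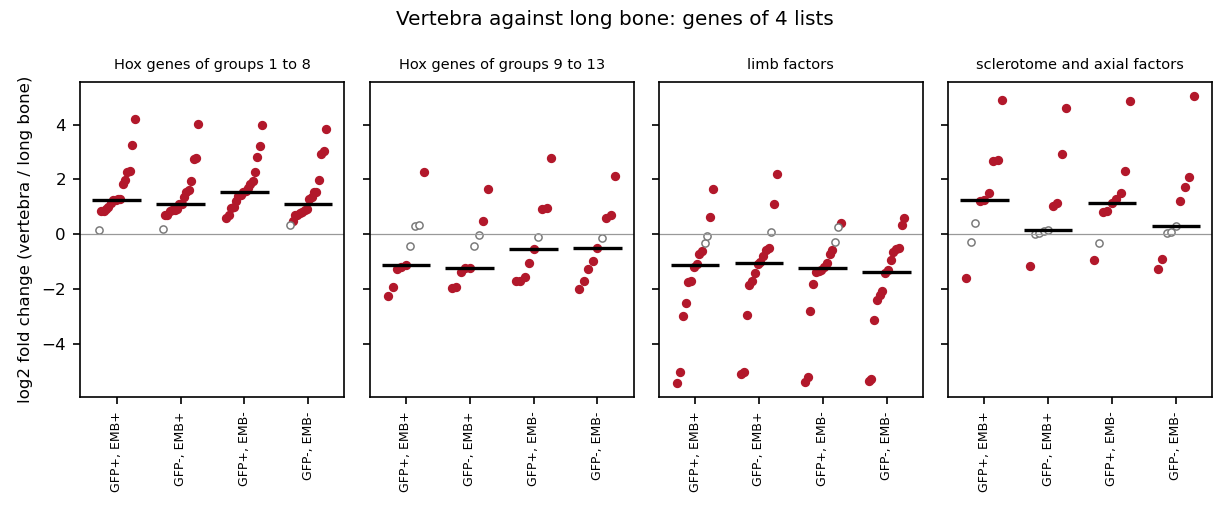
Log2 fold change of vertebral against long bone cells (vertical axis) for each gene of 4 lists, by GFP and EMB state, 4 libraries per group. Red points passed an adjusted p of 0.05, white points did not, and lines are list medians. Medians of the Hox genes of groups 1 to 8 lie between 1.10 and 1.55 and those of the limb factors between -1.36 and -1.05, and the medians of both lists kept these signs after median-ratio scaling.

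Position genes separated the sites in EMB- cells as well. Pax1 averaged 130.4 ± 9.68 FPKM in vertebral GFP+, 149.9 ± 16.5 in vertebral GFP- and 3.66 ± 1.26 in long bone cells and was higher by 4.85 (SE 0.15, adjusted p = 3.0e-18) and 5.05 (SE 0.15, adjusted p = 1.1e-18). Foxf2, a forkhead factor, was higher by 4.19 (SE 0.16) and 4.92 (SE 0.16), and Cytl1, a secreted protein of cartilage, averaged 2721 ± 582 FPKM in vertebral GFP+ and 161.6 ± 107 in long bone cells. Matn1 was lower by -6.10 (SE 0.19, adjusted p = 3.5e-18) and -6.08 (SE 0.19). Of the genes named in GFP- cells, Cxcl12 (chromosome 6, 117168535 to 117181367) averaged 9.94 ± 4.53 FPKM there and 153.5 ± 22.0 in long bone and was lower by -3.89 (SE 0.21, adjusted p = 1.9e-13), and Myog, the muscle factor myogenin, was lower by -4.20 (SE 0.34).

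All 16 Hox genes of groups 1 to 8 were higher in vertebral GFP+ EMB- cells (median 1.55 and adjusted p = 3.9e-23 and adjusted p = 0.00056 with an estimated correlation) and 15 in GFP- EMB- cells (median 1.10 and adjusted p = 4.6e-19 and adjusted p = 0.0017 with an estimated correlation), both also over the list alone. Of 9 sclerotome and axial factors 7 were higher and 1 lower in GFP+ cells (adjusted p = 5.8e-10 and adjusted p = 0.00079 with an estimated correlation), and 4 and 2 in GFP- cells (adjusted p = 1.7e-05 and adjusted p = 0.0155 with an estimated correlation), Pax9, a relative of Pax1, by 2.30 and 2.08. In GFP+ cells this list is again in part set by the sort through Zic1 and Zic4. With the stricter filter, which removes both, 4 of 5 factors were higher there. Of 14 limb factors 11 were lower and 1 higher in GFP+ cells (adjusted p = 0.0018 and adjusted p = 0.104 with an estimated correlation), and 12 and 2 in GFP- cells (adjusted p = 9.0e-05 and adjusted p = 0.028 with an estimated correlation), Shox2 by -5.21 and -5.28. These counts were the same over the list alone.

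Beside them, all 11 erythroid genes were lower in vertebral EMB- cells than in long bone EMB- cells, with medians of -5.61 in GFP+ (adjusted p = 2.8e-11 and adjusted p = 0.104 with an estimated correlation) and -1.67 in GFP- cells (adjusted p = 0.0094 and adjusted p = 0.445 with an estimated correlation, and 0.059 with a pseudocount of 0.1). With quantile normalization 7 were lower in GFP- cells, 10 over the list alone. All 30 cell cycle genes were lower in GFP+ (median -3.20 and adjusted p = 3.0e-21 and adjusted p = 0.120 with an estimated correlation) and 28 in GFP- cells, 29 over the list alone (median -1.20 and adjusted p = 4.0e-06 and adjusted p = 0.397 with an estimated correlation). Of 5 skeletal muscle genes 4 were lower in each, also over the list alone (adjusted p = 0.012 and 0.0055 and adjusted p = 0.179 and 0.109 with an estimated correlation), Tnni2 by -3.81 and -3.89. The first call was lost without long bone EMB- replicate 4 (0.053), and both with the stricter filter (0.088 and 0.089). Of 13 marrow stroma and adipogenic genes 10 were lower in each, with 1 higher over the list alone in GFP+ cells (adjusted p = 0.0040 and 7.9e-05 and adjusted p = 0.120 and 0.028 with an estimated correlation), Lpl, lipoprotein lipase, by -2.49 and -3.02. Leukocyte genes averaged 1.53 ± 0.262 on the log2(FPKM + 1) scale in vertebral GFP+ EMB- cells. They averaged 2.91 ± 0.547 in vertebral GFP- EMB- and 3.32 ± 0.565 in long bone EMB- cells. Of 19 osteoblast genes 15 were lower in GFP+ and 17 in GFP- cells, also over the list alone (adjusted p = 0.0098 and 1.8e-08 and adjusted p = 0.461 and 0.096 with an estimated correlation), Dmp1, an osteocyte protein, by -2.18 and -3.75. In GFP- cells 4 of 6 notochord genes were higher and 2 lower, also over the list alone (adjusted p = 9.6e-06 and adjusted p = 0.0155 with an estimated correlation), T by 2.51.

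In the EMB- state 5623 genes changed between vertebral GFP+ and long bone cells, 871 higher and 4752 lower, and 5676 between vertebral GFP- and long bone cells, 946 higher and 4730 lower. The median gene shifted by -0.27 and -0.28. After median-ratio scaling 2008 were higher and 2805 lower in GFP+ and 1870 and 2659 in GFP- cells, and with quantile normalization 3186 and 2171 and 2484 and 2304, so that the larger side flipped with quantile normalization only. The 16 genes with the largest changes of each kept their direction and call under both. Relative to that shift, by median-ratio scaling, the lists above kept their sign, with 9 osteoblast genes lower in GFP+ cells, 13 over the list alone (8 with quantile normalization), and 17 lower and 1 higher in GFP- cells. Site comparisons that share no libraries called 308 higher and 1030 lower genes in common for vertebral GFP+ EMB+ and GFP- EMB- cells, against 81.8 and 608.5 for independent lists, with 337 going opposite ways. For GFP+ EMB- and GFP- EMB+ cells they called 297 and 796, against 73.9 and 502.7, with 347 going opposite ways. After median-ratio scaling the first pair had 458 and 785 in common, against 161.3 and 330.8, and the second 418 and 585, against 149.8 and 309.4, with 278 and 283 going opposite ways.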

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

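The tests chosen only after the result was seen are the scaling test of the cell cycle genes, both gene length tests and the counts over other splits of the libraries.

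The cell cycle genes went opposite ways with EMB in vertebral GFP+ cells and long bone, with medians of 1.64 and -1.98, and scaling of the FPKM values is argued against, because with median-ratio scaling the long bone median stayed at -2.04. RNA of erythroid cells, present despite the gate against Ter119 and CD45, stays open for the excess of these genes in the vertebral GFP- and long bone EMB- groups: measured over vertebral GFP+ EMB- cells, the vertebral GFP- excess was a median 0.326 of the long bone excess for 30 cell cycle genes (quartiles 0.307 and 0.348, range 0.257 to 1.503), within the 0.260 to 0.344 of the 11 erythroid genes. It leaves out the rise in vertebral GFP+ EMB+ cells, whose erythroid genes had a median change of -0.53. Hbb-bs, the most abundant erythroid list gene, averaged 332.9 FPKM even in vertebral GFP+ EMB- cells, 4270.5 in vertebral GFP- EMB- and 14982 in long bone EMB- cells, and 8 of the 11 erythroid and 25 of the 30 cell cycle genes averaged 1 FPKM or more in the first of these, with none on another list. A difference in cycling between the sorted groups stays open too and was not tested.

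Notochord genes were higher in vertebral GFP- than GFP+ cells, and leukocyte genes moved with them in EMB+ cells. A single carry-over bringing both would make their levels vary together from library to library. Over the 8 vertebral GFP- libraries the deviations of the mean notochord and mean leukocyte levels correlated at -0.216 (exact two-sided permutation p = 0.663 over 576 permutations within groups, Spearman -0.452, exact p = 0.326). Leaving out each library gave -0.502 to -0.0245, and leaving out the 2 farthest gave 0.218. No joint variation was seen, but the notochord levels varied little within groups (SD of deviations 0.195, against 0.677 for the leukocyte levels). These 8 libraries therefore cannot decide it, and a single carry-over stays open. In vertebral GFP- EMB+ cells all 6 tested notochord genes averaged 1 FPKM or more, the most abundant being Cd24a (251.1) and Krt8 (44.8), and in GFP+ EMB+ cells 2 did, while 16 of 17 and 14 of 17 leukocyte genes did, S100a8 at 763.0 and 49.8, although the gate was against CD45, and no other list holds any of these genes. Of the notochord genes, 2 also did so in vertebral GFP+ EMB- and long bone EMB- cells and 3 in long bone EMB+ cells. T averaged at most 0.491 FPKM in these groups, so the list does not measure notochord RNA alone. Notochord cells among the GFP- cells, which no sort marker removes, stay open as untested.

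Long bone EMB- replicate 4 stood apart. It had 15069 genes above 0, fewer than 15121, 15205 and 15306 in the others of its group, which lower depth would give. The gap was small, though. No vertebral library had more than 15029, and the long bone EMB+ libraries had 14914 to 15207, so this does not settle its depth. Its deviation correlated with transcript length at -0.498 by rank, larger in size than in any of the other 23 libraries (highest 0.426), which gene length bias would give (99.86% of genes have a length). Removing the length trend lowered the SD of its deviations only from 0.681 to 0.587. The 20 libraries of the other groups then had 0.232 to 0.299. This test was first set against all 23 other libraries (highest 0.414, undecided). It was changed after that was seen, because the others of its group are measured against it. Length was that of the longest annotated transcript of a gene, so removing its trend can leave length bias behind. The test therefore cannot decide whether length bias is the whole cause. The FPKM of this library summed to 569545, against 416524 to 454785 in the others of its group. No biological explanation was tested.

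Single libraries lay apart from the other 3 of their group in 12 tests, by a gap to the nearest library above Dixon's 95% critical value, which chance gives in about 1 in 20 groups. In all 154 tests were made, of which chance would pass about 7.7, and in 7 of the 12 the other 3 libraries were all listed at 0, so that any value above 0 passes. The sum of FPKM was 433700 in vertebral GFP- EMB+ replicate 2, against 452600, 454400 and 454500. Pitx1 was 0.0340 FPKM in vertebral GFP+ EMB- replicate 3, with the others listed at 0. Mpo was 12.5 FPKM in long bone EMB- replicate 4, against 0.483, 2.02 and 1.06. Bglap was 270.9 FPKM in vertebral GFP+ EMB+ replicate 2, against 424.9, 448.8 and 452.6. Zic4 was 2.838e-08 FPKM in vertebral GFP- EMB+ replicate 4 and 0.296 in vertebral GFP- EMB- replicate 2, and Serpina1e was 0.164 in long bone EMB- replicate 3, each with the others of its group listed at 0. T was 0.176 FPKM in vertebral GFP+ EMB+, 0.117 in long bone EMB+ and 0.0189 in long bone EMB- replicate 3, with the others listed at 0, and 3.47 in vertebral GFP- EMB- replicate 3, against 5.23, 5.13 and 5.31. Mfge8 was 2213 FPKM in vertebral GFP- EMB- replicate 3, against 2470, 2430 and 2461.

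The EMB difference between vertebral GFP+ cells and long bone differed for 3594 genes, led by Ctse (5.95), Klf1 (5.91), Slc4a1 (5.87), Hba-a1 (5.82) and Tspan33 (5.78) on the log2 scale and, in the other direction, Msmp (-9.51), Cilp (-4.07), Abi3bp (-3.75), Padi2 (-3.66) and Sbsn (-3.60). Between vertebral GFP+ and GFP- cells it differed for 573 genes, led by Slc4a1 (4.73), Ctse (4.64), Car2 (4.49), Klf1 (4.36) and Hba-a1 (4.22) and by Cck (-3.19), Hopx (-2.59), Thbs4 (-2.52), Fcnb (-2.50) and Ctsg (-2.41). The call of Ctsg was lost without vertebral GFP- EMB- replicate 1 (adjusted p = 0.0545) or 2 (0.0554), with pseudocounts of 0.1 (0.247) and 5 (0.0734) and with no filter (0.0554).

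Other splits of the libraries were counted for each comparison, 35 of 8 libraries each, and in each only the real split, 1 of 35, gave as many genes. Where replicate numbers were not taken to pair the libraries, in 6 comparisons, this share is under 0.05. It is the smallest that 35 splits can give. It speaks against chance only as far as the libraries are independent, which nothing shows. The other splits also mix the compared groups, which widens the spread where these differ and lowers their counts. The real count and the highest other were 5882 and 1 for EMB in vertebral GFP+ cells and 3941 and 1688 in long bone. For vertebral GFP+ against long bone they were 2531 and 3 in EMB+ cells and 5623 and 2407 in EMB- cells. For vertebral GFP- against long bone they were 2243 and 1 in EMB+ cells and 5676 and 1853 in EMB- cells. Where a comparison holds long bone EMB- cells, the highest other split called many genes (1688, 2407 and 1853). Each of these splits parted long bone EMB- replicate 4, the library that stood apart, from replicates 1, 2 and 3. For EMB in vertebral GFP+ cells, and for vertebral GFP+ and GFP- against long bone in EMB- cells, 3 of 4 same-numbered pairs correlated above 0.1. For these and for EMB in long bone the share holds only as far as the libraries are unpaired. The 8 splits that part all pairs would be too few (highest other 0, 389, 1323 and 1593, in this order). For the 3 comparisons with paired numbers, the 8 splits that part all 4 pairs are too few for a share under 0.05. The real count and the highest other among them were 6152 and 0 for EMB in vertebral GFP- cells and 247 and 1 and 997 and 0 for GFP in EMB+ and EMB- cells, and the other 27 splits, which leave some pair together, gave at most 1, 1 and 0. For the differences, 100 splits were counted, the real one among them. For the first, 2 of 100, again with the real one, gave at least the real 3594 genes (highest other 4194). For the second, only the real split, 1 of 100, gave 573 (highest other 530). Both highest counts came from exchanging all EMB- libraries of the compared populations and 1 EMB+ library of each. A full exchange of the EMB- libraries turns the difference of differences into the difference between the populations, so these splits do not measure what chance gives for it.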

How the results depend on the processing

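Chosen only after the data were seen were the alternatives without long bone EMB- replicate 4 in comparisons that do not hold its group, the list tests with a library left out, and the block and pairing check from title codes. Counts of changed genes and correlations were kept in 219 alternatives, and counts moved by more than 1.5 times in 13, and the cause was not tested. For EMB in vertebral GFP+ cells, median-ratio scaling gave 3246 and quantile normalization 3325 genes, against 5882, and for EMB in long bone the fit of its 8 libraries gave 2059 against 3941. For GFP in EMB+ cells the stricter filter gave 136, library weights 451 and the replicate block 808 genes, against 247, and in EMB- cells weights gave 1672 and the block 2175, against 997. For the EMB difference between vertebral GFP+ and GFP- cells, the fit of its groups gave 1150, weights 1224, the block 1850 and leaving out long bone EMB- replicate 4 900 genes, against 573. Where replicate numbers pair the libraries, the block also brought calls of Cd200 for EMB in vertebral GFP- cells (adjusted p = 5.4e-05) and for GFP in EMB- cells (0.00014) and of Mfge8 for EMB in vertebral GFP- cells (0.0034). The calls of Cd200 do not hang on the pairing. Library weights (0.0041 and 0.0089), only the compared groups in the fit (0.0021 and 0.0066) and leaving out long bone EMB- replicate 4 (0.0025 and 0.0078) brought them too. The block changed no other call of a list or gene named for these comparisons beyond those given with the results, except for single calls of Hoxd10, Klf6, Coro1a and Meox2 that it brought and of Calml3 that it ended (adjusted p = 0.0953). Each of these single calls also changed with other alternatives.

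Vertebral GFP+ EMB+ and GFP+ EMB- cells both pair with both GFP- groups, and running codes in the titles place the libraries of each number side by side. Between EMB+ and EMB- vertebral GFP+ cells, however, only 3 of 4 pairs with the same number correlated above 0.1. Replicate 2 did not (0.097, against 0.126 with another number), so by the rule these were not taken as paired. Nor were those of long bone EMB- cells (lowest -0.297). There the replicate block gave 7418, 4386 and 3861 genes for EMB in vertebral GFP+ cells and for vertebral GFP+ and GFP- against long bone in EMB- cells, against 5882, 5623 and 5676. In the first of these 6 erythroid genes were lower with the block, against 0 without it (adjusted p of the list 0.00017 and 0.0075). The replicate numbers give no block with long bone EMB+ cells, since all of their titles carry the number 1. Running codes in the titles place each of them beside a long bone EMB- library, but these pairs correlated at 0.0276, 0.236, 0.296 and -0.0971, so they were not taken as paired either. A replicate block from these codes gave 1862 genes for EMB in long bone, against 3941, and 2059 in the same 8 libraries without it. It ended the call of Cd200 (adjusted p = 0.238) and brought calls of the lists of Hox genes of groups 1 to 8 (0.030) and of Schwann cells and neurons (0.0067).

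Leaving out each library gave 5000 to 6751, 5463 to 6944 and 3441 to 4558 genes for the 3 EMB comparisons, up to 339 (and at the lowest 21 higher and 151 lower, without vertebral GFP+ EMB+ replicate 2) and 770 to 1379 for GFP in EMB+ and EMB- cells, 2051 to 3325 and 5050 to 6030 for vertebral GFP+ against long bone in EMB+ and EMB- cells, 1867 to 2794 and 5132 to 5965 for GFP- cells, and 3171 to 4379 and 468 to 900 for the differences. The highest value came each time without long bone EMB- replicate 4. Among single genes and lists, 14977 alternatives kept direction and call, 272 lost a call, 158 gained one, 287 without a call moved and 2 reversed. The stricter filter left fewer list genes to test, so that 7 or 8 Hox genes of groups 1 to 8 were higher and 6 or 7 limb factors lower in the site comparisons, and 2 skeletal muscle genes were lower where 4 had been. Mfge8 in EMB+ against EMB- vertebral GFP+ cells changed from 0.02 to -0.37 with median-ratio scaling (adjusted p = 0.0422). That scaling also lowered the 16 genes with the largest changes in this comparison by 0.21 to 0.39, so the turn of Mfge8 has the size of that shift. The meninges list for the difference between vertebral GFP+ and GFP- cells turned with the stricter filter (adjusted p = 0.0142, against 0.816), and the cause of this was not tested. Depth is unknown, so genes of low FPKM carry an error that is only seen between replicates.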

Other observations

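These list tests were planned, except for the counts with a library left out, and which lists to describe was chosen after the results were seen. The pathway genes of Hedgehog signalling and the posterior Hox genes also differed with EMB in the vertebra. In GFP- cells 6 of 12 Hedgehog genes fell and 2 rose in EMB+ cells, 6 and 3 adjusted over the list alone (adjusted p = 0.00080 and adjusted p = 0.343 with an estimated correlation), or 7 and 4 with the replicate number as a block. Gas1, a Hedgehog co-receptor, fell by 3.83 and the forkhead gene Foxf2, a Hedgehog target, fell by 2.97, while Ptch1, the receptor that Hedgehog signalling induces, rose by 2.21. In GFP+ cells 4 fell and 3 rose, 5 and 3 over the list alone, and 6 fell and 1 rose after median-ratio scaling, while 5 rose with library weights or the replicate block. The list tested as lower (adjusted p = 0.0075 and adjusted p = 0.656 with an estimated correlation), although its median was 0.01 and its mean -0.40, with Ptch1 up by 2.22. Of 9 Hox genes of groups 9 to 13, 5 fell in GFP+ EMB+ cells, and 3 fell without EMB+ replicate 1 or EMB- replicate 3 (median -0.45, adjusted p = 0.00022 and adjusted p = 0.323 with an estimated correlation) and 3 in GFP- EMB+ cells (median -0.33, adjusted p = 0.0025 and adjusted p = 0.343 with an estimated correlation, and 0.060 with no filter), both also over the list alone. In GFP- cells 6 fell after median-ratio scaling and 5 with quantile normalization. Hoxd9 was among the genes that fell in both, with -0.92 and -0.91.

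Between the sites, Wnt pathway genes differed in EMB+ cells of vertebra and long bone. Of 13 Wnt pathway genes 8 were lower and 3 higher in GFP+ cells, also over the list alone, with 1 higher without long bone EMB+ replicate 1 or 2 (adjusted p = 0.014 and adjusted p = 0.048 with an estimated correlation). In GFP- cells 7 were lower and 2 higher, 8 and 3 over the list alone (adjusted p = 0.022 and adjusted p = 0.063 with an estimated correlation, and 0.052 with the stricter filter). Sfrp2, a secreted Wnt antagonist, changed by -2.93 and -2.45 and Sfrp1 by -2.68 and -1.77, while Notum, a Wnt-inactivating enzyme, was higher by 2.17 and 1.84. In EMB- vertebral cells, 4 of 7 Schwann cell and neuron genes were lower in GFP+ than in GFP- cells, also over the list alone, and 2 without GFP- EMB- replicate 1 or 3, with a pseudocount of 5, with the stricter filter or with only the compared groups in the fit (adjusted p = 0.014 and adjusted p = 0.171 with an estimated correlation, and 0.069 in that fit), with the myelin gene Mbp at -3.30.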
